A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

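Total RNA from 4 yeast cultures (Saccharomyces cerevisiae S288c), 2 with FLO1 under a galactose-inducible promoter (pGAL-FLO1) and 2 wild type, was analysed on Affymetrix S98 arrays. Per the labels' protocols, samples were taken after 24 h of growth in medium with 2% galactose, 2% raffinose, 2% peptone and 1% yeast extract, RNA was extracted with phenol and chloroform and purified on columns with a DNase step, and labelling followed the manufacturer. Group and replicate number came from the sample titles, and the series' design text calls the replicates biological.

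The deposited values are linear intensity values, 1 per probe set and array. Per the submitters' processing notes they come from GCOS, the array maker's software; its version, settings and detection calls are not given in the sources used here. The 2% trimmed mean was 150.1 on every array, so the arrays had been scaled to a common level by the authors, and the values were used as deposited because these means lay within 10% of each other. Scaling to a common mean makes every change relative: a rise in some abundant transcripts lowers the others. The file holds zeros (14 to 34 per array), so 1 was added before taking log2, and a fold change on that log2(signal + 1) scale understates the change of dim genes.

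Of 9335 probe sets, 60 controls of the manufacturer were left out, as were the 2319 of the remaining 9275 whose mean log2 value lay under the 25th percentile (a signal of 7.65), which left 6956. Gene names came from the platform annotation supplied with the data: 6504 probe sets named 1 gene, 328 several and 2443 none. All 6504 were matched by gene identifier to the current yeast gene table (assembly R64), used for names and for neighbourhood only. The array files name no genome build, so no coordinates are given. No gene was named from a probe set with several. A gene with several probe sets was represented by that with the highest mean log2 value; 250 genes had several, and for 11 of them (APE2, DDR48, FLO10, KCC4, NHP6A, PPT1, RDN37-1, RRT8, SCW10, SRS2 and YDR444W) probe sets were called in opposite directions. Probe sets with the suffixes s, f, i, r, g or x can share probes or sequence with other transcripts.

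The groups were compared with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 6956 probe sets and a threshold of 0.05. With 2 arrays per group the fit has few residual degrees of freedom of its own, so the p-values lean on the spread shared between probe sets (prior degrees of freedom 7.12). Replicates correlated at 0.992 (pGAL-FLO1) and 0.990 (wild type) across probe sets on the log2 scale, and arrays of different groups at 0.854 to 0.867; probe sets are not independent replicates.

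For background, 19 probe sets for bacterial and mouse genes served as non-yeast controls; their highest signal was 4.1 and 5.2 on the pGAL-FLO1 arrays and 9.7 and 3.6 on the wild-type arrays, and 83.3%, 80.1%, 72.6% and 82.9% of the probe sets lay above it. This level was chosen after the data were seen. Where a probe set lay at or under it on both arrays of a group, its fold is given as a lower bound against that level, from means of log2 signals without the added 1. For FLO1 the fitted log2 value stands beside the bound. Values at that level have no order.

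Before the data were examined, 44 gene lists were written from general knowledge of yeast (1318 entries, 4 of which matched no current gene), and the 43 with at least 4 measured genes were tested with limma's camera (preset correlation 0.01, 1 probe set per gene), adjusted over the lists. Some lists were measured in part only: 18 of 42 meiosis genes, 10 of 24 PAU genes, 11 of 26 hexose transporters and 80 of 137 cytosolic ribosomal proteins. The filter uses the mean over all 4 arrays, so a gene that is dim in 1 group passes more readily if it is high in the other. fry, camera with an estimated correlation, and 10000 random lists matched on mean value were run as alternatives. The estimated correlation, and the test that uses it, rest on the few residual degrees of freedom of 4 arrays. The genes named in the text were also set beforehand: FLO1; the 12 largest rises and 12 largest falls among called probe sets that name exactly 1 gene and in which both arrays of a group lay above both of the other, by fitted log2 value and counting probe sets other than a gene's brightest; every measured flocculin, galactose and auxotrophic marker gene; for each list past the camera test the 4 called members that moved most in its direction; and for other lists at most 2 called members. Exceptions are named as such.

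Alternatives fixed beforehand were quantile normalization, median centring, a larger added constant, other filters on dim probe sets, a block for replicate number, other variance models, leaving out suffixed probe sets, leaving out each array in turn, and other thresholds and set tests. Spike-in scaling (9 hybridisation controls) and lists on unsuffixed probe sets floored at the control level were added after the data were seen. The procedure was tested on simulated data for pGAL-FLO1 against wild type, with 200 of 6956 probe sets changed. All 200 were drawn from those at or above the median wild-type log2 value, so recovery among dimmer probe sets was not simulated. It recovered 30.3% of those changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2. Of 162 calls, 9 were false. Far fewer probe sets changed in this simulation than were called in the data. In a simulation with 3 shifted lists over 5214 genes, camera called all 3 and no other list with the preset correlation, and 2 of the 3 with the estimated correlation. Figures were drawn with matplotlib 3.10.9.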

Results

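RNA was measured in 2 groups of budding yeast cultures of the laboratory strain S288c. In the pGAL-FLO1 group, FLO1 was placed behind a galactose-inducible promoter. FLO1 encodes a cell-surface adhesin whose binding of mannose chains on neighbouring cells makes yeast clump into flocs. The other group was the wild type, which does not flocculate. Each group had 2 biological replicates, grown for 24 h in rich medium with 2% galactose and 2% raffinose to what the sample titles call stationary growth, and each replicate was hybridised to 1 Affymetrix S98 expression array. The number of arrays, 2 per group, limits the precision of every value. The scaled signals had medians of 37.1 and 37.6 on the pGAL-FLO1 arrays and of 34.6 and 34.0 on the wild-type arrays. The question was how gene expression differs between flocculating and non-flocculating cells. All samples were taken at a single time, and no measure of culture density or growth was used here. A difference in growth stage between the groups therefore cannot be told apart from a difference due to flocculation.

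FLO1 itself was present in the pGAL-FLO1 cultures and was not above background in the wild type. Its probe set read 1456 and 1318 on the pGAL-FLO1 arrays (mean 1387 ± 97.4, SD, n = 2) and 0.3 on each wild-type array, where the highest non-yeast control probe sets read 9.7 and 3.6. The log2 fold change was 10.06 on the log2(signal + 1) scale (SE 0.15, limma adjusted p = 4.5e-10). With wild-type signals raised to the non-yeast control level, FLO1 was at least 234-fold higher in pGAL-FLO1. This probe set carries a suffix for probes that can be shared with other sequences.

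Other flocculin probe sets gave mixed values. A FLO5 probe set rose from 4.20 ± 2.69 in the wild type, not above background, to 409 ± 26.4 in pGAL-FLO1 (SD, n = 2, at least 69.1-fold, adjusted p = 1.7e-07). The FLO5 probe set without a shared suffix read only 0.9 and 1.2 on the pGAL-FLO1 arrays and 7.0 and 4.5 on the wild-type arrays, and another with a shared suffix read 6.2 and 12.8 against 7.1 and 0.7. Both were too dim to be tested. No probe set named FLO9 alone. FLO10 rose by its brightest probe set, which has a shared suffix (log2 fold change 1.31, adjusted p = 2.3e-04). Of the 3 other FLO10 probe sets tested, one with such a suffix (2.08) and one without (1.41) rose, and another without it fell by 0.65 (adjusted p = 0.036). A further one without a suffix, too dim to be tested, read 9.6 and 10.5 in pGAL-FLO1 against 1.8 and 0.3. FLO11, the adhesin of invasive and pseudohyphal growth, went from 32.3 ± 12.5 to 50.5 ± 12.1 (log2 fold change 0.66, adjusted p = 0.048). That call was lost when pGAL-FLO1 replicate 1 (adjusted p = 0.319), pGAL-FLO1 replicate 2 (0.054) or wild-type replicate 2 (0.297) was left out, with the FLO11 value between 0.27 and 1.06 over the arrays left out, under quantile normalization (0.108) or median centring (0.088), and in 3 further alternatives. AGA1, the anchor of the mating agglutinin, fell by 0.82 (adjusted p = 4.0e-04). FIG2 stood at -0.21 (adjusted p = 0.415), and between -0.31 and -0.11 with each array left out in turn. Of the 6 measured flocculins, 4 were higher and 1 lower, also when adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.141).

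**Figure D1:**
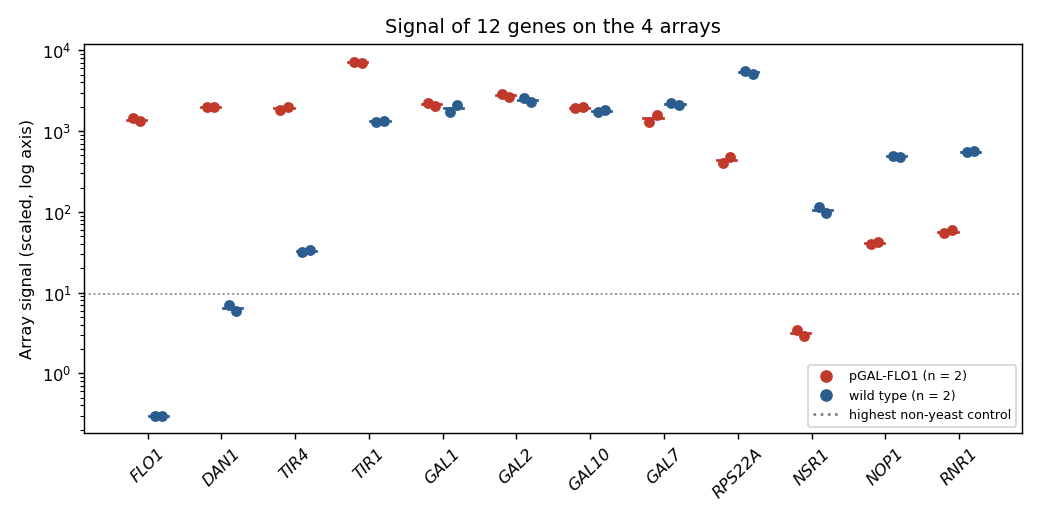
Array signal (log axis) of 12 genes, a pair of points per group for the replicates (n = 2) and a bar at their mean; the dotted line is the highest signal of any non-yeast control probe set (9.7). FLO1 and DAN1 lie below that line in the wild type and far above it in pGAL-FLO1, NSR1 shows the opposite arrangement, and the GAL1, GAL2 and GAL10 signals of the groups lie close together.

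Most of the transcriptome differed between the groups. Of 6956 probe sets tested, 4638 passed an adjusted p of 0.05, with 2711 higher and 1927 lower in pGAL-FLO1, and 1172 of the higher and 961 of the lower ones changed at least 2-fold. Counted with 1 probe set per gene, 1895 of 5214 genes were higher and 1632 lower. Both arrays of one group lay above both of the other in 5858 probe sets (84.2%, where chance gives 33.3%). The median difference between replicates was 0.14 (pGAL-FLO1) and 0.16 (wild type) on the log2 scale, against a median difference between groups of 0.64. The median log2 fold change of all tested probe sets was 0.16 as deposited, 0.08 after quantile normalization, 0.04 after median centring and 0.22 after scaling on spike-in controls. List medians are also given relative to that 0.16, which includes probe sets that name no gene (median 0.52). For genes with 1 probe set each, as used in the lists, the median was 0.07. Relative to genes, the list falls would thus be smaller and the rises larger than those given. The labels describe the biotin label of wild-type replicate 2 in other words than those of the other arrays. Without that array, 2539 probe sets were higher and 1880 lower.

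The rule for the largest changes named 12 probe sets in each direction. Those with a wild-type or pGAL-FLO1 group at the control level have only a bound and no rank: beside FLO1 and FLO5, FAT3 was at least 12.2-fold higher (adjusted p = 3.4e-07), the nucleolar protein gene NSR1, at 105 ± 13.5 in the wild type (SD, n = 2), at least 22.7-fold lower, RPA43, a subunit of RNA polymerase I, at least 12.6-fold lower, and DBP2, a helicase gene, at least 8.43-fold lower by a dim probe set, while its brightest probe set fell by 1.01. The other rises included DAN1, which encodes a cell wall mannoprotein known from anaerobic growth (6.45 ± 0.78 in the wild type against 1978 ± 16.2 in pGAL-FLO1, SD, n = 2, log2 fold change 8.06, SE 0.13, adjusted p = 5.8e-10), and TIR4 (5.82), another cell wall mannoprotein. RGI2 (5.90), a gene of respiratory growth, SPG1 (5.41) and SPG4 (5.11), both known from stationary phase, YNL195C (4.67), YOR186W (4.62) and YNL194C (4.57) rose too. The transketolase gene TKL2 also rose (4.69, and 4.27 by its brightest probe set). Only 1 of the 2 wild-type arrays measured DAN1, SPG1, SPG4 and YOR186W above the control level. The other falls were those of RPS9B (-4.14, and -3.84 by its brightest probe set), the cell wall glycosidase gene UTR2 (-4.08), RPL7B (-3.82), NOP58 (-3.73, and -3.44 by its brightest probe set), URA7 (-3.72), RPA12 (-3.70), ERB1 (-3.70) and ALB1 (-3.69). Only 1 of the 2 pGAL-FLO1 arrays measured RPL7B and ALB1 above the control level. All 24 of these probe sets kept their direction and passed the test in every alternative that gave a value.

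**Figure D2:**
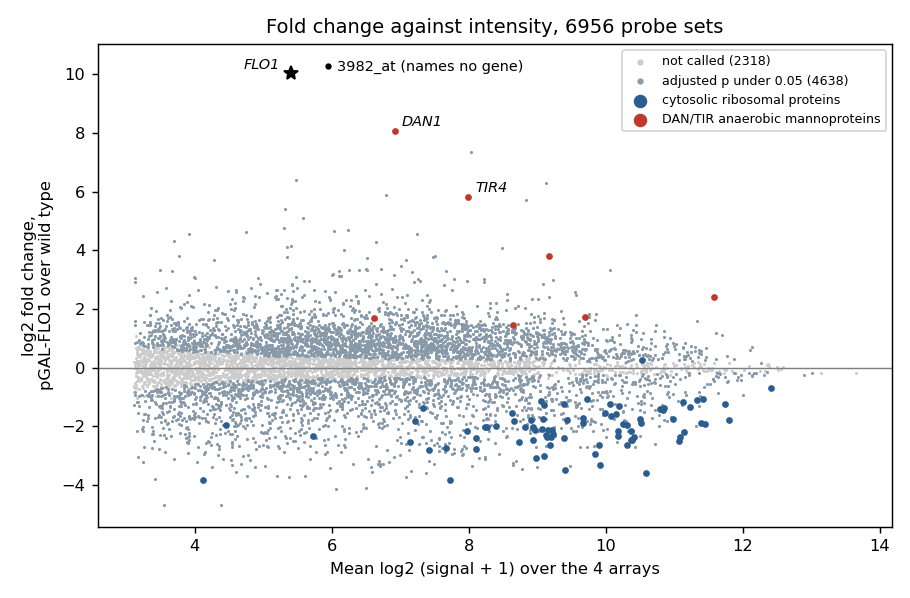
log2 fold change (pGAL-FLO1 over wild type) against mean log2(signal + 1) over the 4 arrays for the 6956 probe sets tested, with the 4638 at an adjusted p under 0.05 in darker grey. Members of the cytosolic ribosomal protein list (blue) lie below 0 at all intensities except RPL15B (0.25), and the DAN/TIR genes (red) lie above 0.

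Genes for making ribosomes were lower in pGAL-FLO1. Of 80 measured genes of cytosolic ribosomal proteins, 79 fell and 1 rose, RPL15B (0.25, adjusted p = 0.030), which was chosen after its value was seen. The list median was -2.03, or -2.19 relative to all probe sets (camera adjusted p = 1.2e-30). RPS22A, for example, went from 5327 ± 324 to 442 ± 53.6 (SD, n = 2, log2 fold change -3.59), and RPS7A fell by 3.50. Of 106 ribosome biogenesis genes, 99 fell, 0 rose and 7 did not pass the test (median -1.97, relative to all -2.13, camera adjusted p = 6.1e-22). The small nucleolar ribonucleoprotein genes NOP1 (-3.54) and GAR1 (-3.54) were among those that fell. Of 26 genes of RNA polymerase I and III and their factors, 21 fell, 4 did not pass and 1 rose (median -1.64, relative to all -1.80, camera adjusted p = 5.6e-06). RPA190, the largest subunit of RNA polymerase I, fell by 3.30 and RPA49 by 3.36. The riser was RRN3 (2.66), a factor that recruits RNA polymerase I and that was chosen after its value was seen. Adjusted over the list alone, the counts were the same in these 3 lists. With an estimated correlation none of them passed (adjusted p = 0.297 for each).

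In contrast, 49 of 72 genes of mitochondrial ribosomal proteins rose, 0 fell and 23 did not pass, also when adjusted over the list alone (median 0.50, relative to all 0.34, camera adjusted p = 7.8e-06, adjusted p = 0.297 with an estimated correlation). The listed genes with the largest rises were MRPS17 (1.33), RSM28 (1.26), MRPS28 (1.12) and MRP8 (1.12). Whether each listed gene encodes a protein of that ribosome was not checked. The difference between the mitochondrial and cytosolic lists was not itself tested.

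Genes of DNA synthesis and of nucleotide and amino acid supply fell as well. Of 37 G1/S and DNA replication genes, 33 fell, 3 rose and 1 did not pass (median -1.39, relative to all -1.55, camera adjusted p = 1.8e-08). The large subunit of ribonucleotide reductase, RNR1, went from 556 ± 9.40 to 56.8 ± 3.46 (SD, n = 2, log2 fold change -3.27), the G1 cyclin gene PCL1 fell by 3.54, the sliding clamp gene POL30 by 3.10 and POL1, a DNA polymerase gene, by 2.89. The risers were RNR3 (1.75), RAD54 (1.11) and ORC1 (0.87), chosen after their values were seen. Of 52 amino acid synthesis genes, 39 fell, 6 rose and 7 did not pass (median -0.91, relative to all -1.07, camera adjusted p = 1.8e-08), led by THR1 (-2.68), BAT1 (-2.59), ASN2 (-2.51) and HIS1 (-2.39). Of 24 purine and pyrimidine synthesis genes, 21 fell, 2 rose and 1 did not pass (median -0.86, relative to all -1.02, camera adjusted p = 1.1e-05), with URA7 (-3.72), GUA1 (-2.86), FUR1 (-2.83) and IMD4 (-2.44) lowest. Adjusted over the list alone, the counts in these 3 lists were the same. The adjusted p with an estimated correlation was 0.305 for G1/S genes and 0.297 for each of the other two.

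Ergosterol synthesis genes and the phosphate regulon were lower by a smaller margin. Of 26 ergosterol genes, 15 fell, 3 rose and 8 did not pass (median -0.39, relative to all -0.55, camera adjusted p = 0.038, adjusted p = 0.334 with an estimated correlation). ERG13 (-1.58), ERG2 (-1.54), MVD1 (-1.38) and CYB5 (-1.20) fell most. That list's call was lost under quantile normalization (adjusted p = 0.058), spike-in scaling (0.181) and without wild-type replicate 1 (0.058). Of 16 phosphate regulon genes, 10 fell, 3 rose and 3 did not pass (median -0.48, relative to all -0.64, camera adjusted p = 0.029, adjusted p = 0.476 with an estimated correlation). PHM6 (-1.90) and PHO3 (-1.84), an acid phosphatase gene, fell most, with VTC3 (-1.19) and VTC4 (-0.96), which make polyphosphate. Spike-in scaling ended the list's call (adjusted p = 0.113). The counts of both lists were the same when adjusted over the list alone.

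Cell wall mannoprotein genes of the DAN/TIR and PAU families were higher. All 7 measured DAN/TIR genes rose (median 2.42, relative to all 2.26, camera adjusted p = 1.7e-05), as did all 10 measured PAU genes (median 2.35, relative to all 2.19, camera adjusted p = 9.4e-06), also when adjusted over the list alone. PAU23 stands in both lists. TIR4 went from 33.0 ± 1.06 to 1915 ± 93.3 and TIR1 from 1323 ± 16.7 to 7071 ± 230 (SD, n = 2, log2 fold changes 5.82 and 2.42). PAU23 (3.82), PAU7 (3.33), PAU17 (3.31) and PAU3 (2.42) led the PAU list, whose probe sets all carry a shared-sequence suffix. The adjusted p with an estimated correlation was 0.297 for both lists. Of 21 hypoxic genes fixed as a separate list, 12 rose, 5 fell and 4 did not pass, also when adjusted over the list alone, and the list did not pass the set test (median 0.63, camera adjusted p = 0.110), though it passed as higher with fry (adjusted p = 0.010) and against matched random lists (99.4 percentile). PDR11 (2.66) and YGR035C (2.02) rose most. Among the other members, chosen after their values were seen, AAC3 (-1.14), FRD1 (-0.81) and ANB1 (-0.77) fell. Chosen in the same way, CYC7 (1.66), AUS1 (1.36), SUT1 (1.20), OLE1 (0.74) and COX5B (0.59) rose, and HEM13 stood at 0.00 (adjusted p = 0.982).

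Cell separation genes, most of them known for expression in daughter cells, were higher: of 13 measured, 12 rose and 1 did not pass, also when adjusted over the list alone (median 1.39, relative to all 1.22, camera adjusted p = 3.5e-05, adjusted p = 0.297 with an estimated correlation). The glucanase gene DSE4 went from 88.7 ± 0.71 to 702 ± 54.9 (SD, n = 2, log2 fold change 2.97), and DSE3 (2.30), ASH1 (2.02), a daughter-specific repressor, and EGT2 (1.72) rose with it. Cell wall integrity genes showed no common direction, with 15 of 37 higher, 15 lower and 7 not past the test (15 and 16 adjusted over the list alone, median 0.04, mean -0.01, camera adjusted p = 0.746). SCW10 (-3.18, with another probe set called in the opposite direction) and PIR3 (2.57) changed most.

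Stress and reserve genes rose together. Of 34 general stress genes driven by Msn2 and Msn4, 28 rose, 2 fell and 4 did not pass (median 1.21, relative to all 1.05, camera adjusted p = 1.5e-07). The aldehyde dehydrogenase gene ALD3 (3.72), ROQ1 (3.27), RTN2 (2.66) and SIP18 (2.60) led. Of 26 heat shock chaperone genes, 21 rose, 1 fell and 4 did not pass (2 fell when adjusted over the list alone, median 0.99, relative to all 0.82, camera adjusted p = 5.6e-06), with SSA3 (3.34), BTN2 (2.49), HSP26 (1.79) and AHA1 (1.70) highest. Of 20 trehalose and glycogen genes, 15 rose, 1 fell and 4 did not pass (median 0.66, relative to all 0.50, camera adjusted p = 0.0010), including PIG2 (2.04), GLG1 (1.47), ATH1 (1.37) and NTH2 (1.25). Of 31 oxidative stress genes, 20 rose, 3 fell and 8 did not pass (5 fell when adjusted over the list alone, median 0.49, relative to all 0.33, camera adjusted p = 0.0047). TSA2, a peroxiredoxin gene, went from 86.2 ± 7.14 to 1467 ± 20.6 (SD, n = 2, log2 fold change 4.08), ahead of OYE3 (2.50), GPX1 (2.35) and GND2 (2.19). For general stress and for trehalose and glycogen the counts adjusted over the list alone were the same. With an estimated correlation the adjusted p was 0.297 for each of these 4 lists.

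Genes of fat and C2 carbon use and of self-digestion were higher too. Of 24 gluconeogenesis and glyoxylate cycle genes, 18 rose, 2 fell and 4 did not pass (median 1.07, relative to all 0.91, camera adjusted p = 2.0e-04, adjusted p = 0.321 with an estimated correlation), with PCK1, the first enzyme of gluconeogenesis, at 2.84, IDP2 at 2.66, CRC1 at 2.43 and CAT2 at 2.26. Of 30 peroxisome and beta-oxidation genes, 23 rose, 3 fell and 4 did not pass (median 0.84, relative to all 0.68, camera adjusted p = 8.2e-04, adjusted p = 0.350 with an estimated correlation). The thiolase gene POT1 (3.21), POX1 (2.03) and MLS1 (1.98) rose most with CAT2. Of 27 autophagy genes, 21 rose, 0 fell and 6 did not pass (median 0.74, relative to all 0.58, camera adjusted p = 2.2e-04), among the higher ones ATG10 (3.05), ATG1 (1.84), ATG7 (1.60) and ATG14, which was at the control level in the wild type and at least 3.38-fold higher in pGAL-FLO1. Of 34 proteasome genes, 21 rose, 1 fell and 12 did not pass (median 0.37, relative to all 0.20, camera adjusted p = 0.0024, lost under spike-in scaling at 0.054 and against matched random lists, at the 92.1 percentile), among them RPN4 (1.28), the transcription factor of proteasome genes, RPN11 (1.10), RPN6 (1.08) and RPN5 (1.04). The autophagy and proteasome lists had an adjusted p of 0.297 with an estimated correlation, and all 4 lists had the same counts when adjusted over the list alone.

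Further lists passed upward. Of 20 multidrug transport genes, 16 rose, 1 fell and 3 did not pass (median 0.77, relative to all 0.61, camera adjusted p = 0.0010), with PDR15 (2.52), AQR1 (2.44, or 3.43-fold with signals raised to the control level, which 1 of 2 wild-type arrays exceeded), PDR10 (2.05) and CIS1 (2.00) among the higher ones. Of 27 iron regulon genes, 18 rose, 4 fell and 5 did not pass (median 0.62, relative to all 0.46, camera adjusted p = 0.034), including the metalloreductase gene FRE2 (2.03, above the control level on 1 of 2 wild-type arrays), MRS4 (1.95), FIT2 (1.79) and ISU1 (1.29). The call was lost with the filter at the 50th percentile (adjusted p = 0.103) and under spike-in scaling (0.105). Only 18 of the 42 listed meiosis and sporulation genes were measured. Of 18 meiosis and sporulation genes, 10 rose, 1 fell and 7 did not pass (9 rose when adjusted over the list alone, median 0.71, relative to all 0.55, camera adjusted p = 0.045), with SGA1 (1.83), RIM4 (1.16), REC107 (1.10) and IME1, the master regulator of meiotic entry, which went from 23.7 ± 3.96 to 68.95 ± 14.6 (SD, n = 2, adjusted p = 1.1e-04), among the higher ones. Leaving out pGAL-FLO1 replicate 1 (adjusted p = 0.052) or wild-type replicate 2 (0.079) ended the meiosis call, as did testing without the filter on dim probe sets (0.189) and 5 other alternatives. With an estimated correlation the adjusted p was 0.297 for the multidrug and iron lists and 0.305 for meiosis. The multidrug and iron counts were the same when adjusted over the list alone.

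**Figure D3:**
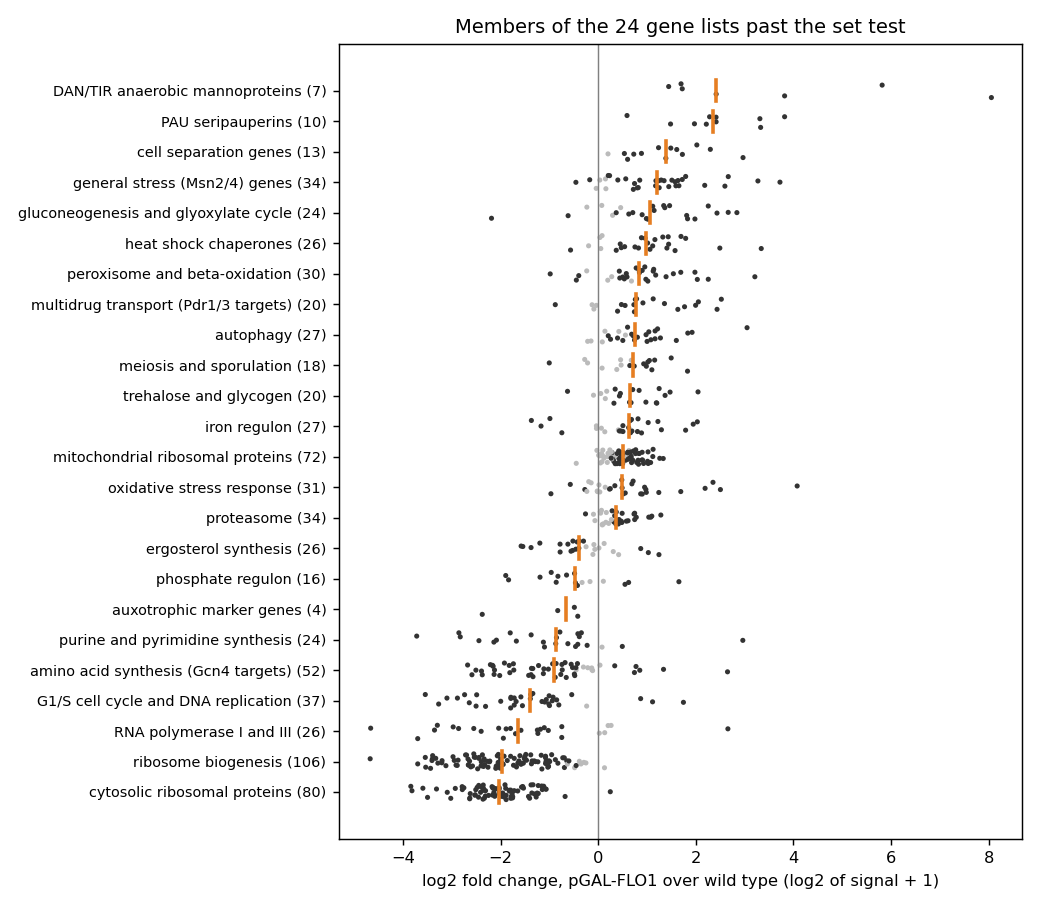
log2 fold change (pGAL-FLO1 over wild type) of each measured member of the 24 gene lists that passed the camera test, with the number measured in parentheses; black points passed an adjusted p of 0.05, grey points did not, and orange bars are list medians. The medians run from -2.03 for cytosolic ribosomal proteins to 2.42 for DAN/TIR genes.

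GAL1, GAL2, GAL7, GAL10, GCY1 and PGM2 lay far above the array medians in both groups. GAL1 read 2138 ± 94.4 in pGAL-FLO1 and 1926 ± 254 in the wild type (SD, n = 2, log2 fold change 0.16, adjusted p = 0.177), and GAL2 (0.20, adjusted p = 0.051), GAL10 (0.14, adjusted p = 0.123), GCY1 (0.13, adjusted p = 0.280) and PGM2 (0.05, adjusted p = 0.642) did not pass the test either. Quantile normalization put GAL1 (0.34), GAL2 (0.39), GAL10 (0.34) and GCY1 (0.32) past the threshold as higher. With each array left out in turn, GAL1 lay between 0.02 and 0.29 (highest without wild-type replicate 2). GCY1 then lay between -0.014 and 0.27 (highest without pGAL-FLO1 replicate 1) and GAL2 between 0.12 and 0.27 (highest without wild-type replicate 1). Each passed the test at that highest value, and GAL2 also in 5 further alternatives. GAL7 fell by 0.58 (adjusted p = 6.2e-04), GAL3 by 0.74 (0.0084) and GAL80 by 0.40 (0.0076), while GAL4, the activator, rose by 0.70 (0.0023). The GAL3 call was lost without either pGAL-FLO1 replicate (adjusted p = 0.060 and 0.052), with values of -0.73 and -0.76, while leaving out a wild-type array moved GAL3 to -1.08 or -0.41. The GAL80 call was lost without pGAL-FLO1 replicate 1 (adjusted p = 0.059) and under spike-in scaling (0.095). Of the 9 members 1 was higher and 3 lower, also when adjusted over the list alone. The list median was 0.13, its mean -0.04 and its camera adjusted p 0.957.

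Genes often used as auxotrophic markers gave the following signals. URA3 read 0.2 on both pGAL-FLO1 arrays and 0.3 on both wild-type arrays, below the non-yeast controls, MET17 was not above background on any array, and LEU2 read at most 12.6 on any array. None of these was tested. HIS3 went from 366 ± 8.70 in the wild type to 69.7 ± 3.46 in pGAL-FLO1 (SD, n = 2, log2 fold change -2.38, adjusted p = 2.3e-07), TRP1 fell by 0.83, LYS2 by 0.49 and ADE2 by 0.42. All 4 measured members thus fell, also when adjusted over the list alone (median -0.66, relative to all -0.82, camera adjusted p = 0.033, adjusted p = 0.305 with an estimated correlation). The list's call ended under spike-in scaling (adjusted p = 0.061) and against matched random lists (7.86 percentile). LYS2 was not called without pGAL-FLO1 replicate 1 (adjusted p = 0.061), pGAL-FLO1 replicate 2 (0.064) or wild-type replicate 2 (0.088, with LYS2 at -0.32), nor ADE2 without pGAL-FLO1 replicate 2 (0.078) or wild-type replicate 1 (0.055), and neither under spike-in scaling (0.0503 and 0.072).

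Genes specific to a mating type formed separate lists. Of 7 a-specific genes, 5 fell, 1 rose and 1 did not pass, also when adjusted over the list alone (median -0.29, camera adjusted p = 0.193). The pheromone receptor gene STE2 fell by 0.92 and ASG7 rose by 0.71. The 3 measured alpha-specific genes were too few for the set test. SAG1 rose (1.71), from 29.2 ± 5.09 to 97.7 ± 13.6, and STE3 fell by 0.67, from 29.95 ± 4.17 to 18.3 on both arrays (SD, n = 2). Both genes lay under the array medians in the wild type. MFA2 and MF(ALPHA)1 were chosen after their values were seen. The a-specific MFA2 was bright in both groups (mean 4399 in pGAL-FLO1, 4972 in the wild type). The alpha-specific MF(ALPHA)1 was dim in both (18.3 and 26.9). The STE3 call was lost without either pGAL-FLO1 array (still at -0.67) or wild-type replicate 1 (-0.54). Spike-in scaling ended it as well (limma adjusted p = 0.0507). The remaining member did not pass, and counts adjusted over the list alone were the same. Of 19 haploid-specific and pheromone response genes, 8 fell and 5 rose (8 and 6 adjusted over the list alone, median 0.09, mean -0.30, camera adjusted p = 0.560), with HO (-3.15), the mating-type switching endonuclease, and FAR1 (-2.23), which arrests the cycle on pheromone, lowest.

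The remaining lists did not pass the set test. Flocculation regulators (camera adjusted p = 0.560) had 2 of 11 higher and 4 lower (1 and 4 adjusted over the list alone), among them STE12 (-1.40) and the corepressor TUP1 (-1.04). Glycolysis (0.108) had 12 of 23 lower and 3 higher, with HXK2 (-1.81) and PDC5 (0.88) most changed. The list of hexose transporters (0.082) had 6 of 11 members higher and 0 lower, including MAL31 (1.84, by a probe set with a shared suffix) and HXT5 (1.11). Whether each member of that list carries hexoses was not checked. In the TCA cycle list (0.999, median -0.01, mean 0.13) 5 of 21 rose and 4 fell (5 and 3 adjusted over the list alone), with CIT2 (3.17) and IDP1 (-1.44) most changed, and in the respiratory chain list (0.925, median -0.01, mean 0.06, direction of the test lower) 10 of 41 rose and 8 fell (8 and 7 adjusted over the list alone), with NDE2 (3.36) and CYC1 (-1.31). G2/M genes (0.746) had 8 of 28 higher and 6 lower (7 and 5 adjusted over the list alone), including HST3 (1.42) and BUB2 (-1.38), and histones (0.077) 3 of 4 lower, including HTB2 (-1.75) and HHO1 (-0.90). Zinc regulon genes (0.567) had 3 of 12 higher and 1 lower, with MCD4 (-1.70) and PST1 (1.36). Sulfur and methionine genes (0.077) had 11 of 27 lower and 5 higher, with CYS3 (-2.32) and HOM3 (-2.13). Nitrogen catabolite repressed genes (0.095) had 18 of 31 higher and 5 lower, with GDH2 (3.02) and GDH3 (2.33). Thiamine genes (0.360) had 7 of 14 higher and 2 lower, with PHO3 (-1.84) and THI72 (1.61). Unfolded protein response genes (0.304) had 10 of 24 lower and 6 higher (11 and 6 adjusted over the list alone), with HRD1 (1.79) and SEC63 (-1.69), and hyperosmotic glycerol genes (0.365) 9 of 18 higher and 4 lower, with ALD3 (3.72) and SIP18 (2.60). Some uncalled lists passed in other settings. With fry 12 of them did, and against matched random lists flocculins (98.55 percentile), nitrogen genes (98.4) and the hypoxic list did. Further cases were flocculins under spike-in scaling (5.5e-07), glycolysis after median centring (0.0496), hexose transporters and sulfur genes after quantile normalization (0.0497 each), hexose transporters without pGAL-FLO1 replicate 2 (0.042), histones without wild-type replicate 1 (0.040) and nitrogen genes with the 50th percentile filter (0.030). Where no other count is given, that adjusted over the list alone was the same.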

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

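The tests in this part were chosen after the results were seen, except the set tests of the hypoxic list and the quantile and median scalings, which were planned.

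A strong signal came from outside the named genes. A probe set that names no gene in the annotation used here had a mean signal of 2180 ± 85.1 in pGAL-FLO1 and of 0.75 ± 0.07 in the wild type (SD, n = 2), where it was not above background. It was at least 369-fold higher (limma adjusted p = 3.0e-10). The report describes genes by name and so does not use it.

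Probe sets that name no gene were mostly higher in pGAL-FLO1: 482 of the 979 tested were called higher and 96 lower, so 83.4% of their calls were upward, against 53.7% for genes. A bias tied to intensity would raise gene-naming probe sets of the same brightness alike, but the unnamed ones were higher more often in all 10 equal bins of mean intensity. The scaling between arrays does not account for it either, since the share stayed at 76.4% or above under quantile, median and spike-in scaling. Of the 339 called unnamed probe sets without a shared suffix, 259 (76.4%) were higher, a smaller share than the 83.4% of all unnamed calls. Probe sets with a shared suffix thus do not account for all of it but may add to it. Sharing among the others is not excluded, since probe sequences were not available. What these probe sets measure stays open, and no biological explanation was tested.

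A probe set that names FLO5 alone read high in pGAL-FLO1 (409), as did a probe set that names FLO5, FLO1 and FLO9 (mean 3331), one that names FLO5 and FLO1 (3325) and one that names FLO5 and FLO9 but not FLO1 (4964). A candidate explanation is that FLO1 transcript hybridised to sequence these genes share: the FLO5 probe set without a shared suffix had a mean of 1.05 on the pGAL-FLO1 arrays, at or under the non-yeast controls there. That probe set exceeded the controls on only 1 of the 2 wild-type arrays, so it may not report FLO5 at all. Shared hybridization and a rise of FLO5 transcript itself therefore cannot be told apart.

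The joint rise of the DAN/TIR and PAU genes was weighed as well. DAN1, DAN4 and TIR1 to TIR4, all on probe sets without a shared suffix, rose by at least 1.44 on the log2 scale. Hybridisation shared within the family, as far as suffixes mark it, therefore does not account for the DAN and TIR part. Probe sequences were not available, so a contribution of sharing that no suffix marks is not excluded. For the PAU part shared hybridisation cannot be told apart from a rise of each gene, since 0 tested PAU probe sets lack such a suffix. Scaling between arrays does not account for either part: the lowest list median under the other scalings was 2.22. Lower oxygen in the pGAL-FLO1 cultures is a biological hypothesis that may explain the rise, as DAN and TIR genes are known for anaerobic induction, but the tests of the hypoxic gene list differed: it did not pass with camera (adjusted p = 0.110) and passed as higher with fry (0.010) and against matched random lists (99.4 percentile), with 12 members higher and 5 lower, so the hypothesis stays open.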

How the results depend on the processing

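Spike-in scaling and the floored lists were added after seeing the data; the other alternatives were planned. Counts of changed probe sets stayed within 1.5 times except under stricter thresholds, which by construction call fewer: limma treat against a 1.5-fold change gave 1205 higher and 962 lower, and a 2-fold minimum 1172 and 961. The share of calls that were higher (58.5%) ranged from 51.0% (median centring) to 62.0% (spike-in scaling). Leaving out each array, the lone one being assumed to vary like the others, gave 2196 to 2632 higher, 1608 to 1880 lower, 57.4% to 59.95% higher, FLO1 at 9.99 to 10.13, 14 to 16 lists higher and 9 lower. The FLO1 value rests on the added constant, as its wild-type signal lay under the controls, so that range does not measure its stability: it went down to 7.48 with the 25th percentile of all values added before log2, and gave no value without suffixed probe sets. With a replicate block, 2663 probe sets were higher and 1887 lower, FLO1 stood at 10.06, and 15 lists were higher and 9 lower; of the named genes the block changed the call of GAL2 alone (0.20, adjusted p = 0.033). The arrays share only a number: deviations of same-numbered arrays correlated at -0.10.

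Gene lists depended on the set test. With an estimated correlation 0 were higher and 0 lower (15 and 9 with the preset correlation), at adjusted p of 0.297 to 0.476 for the 24 called lists; fry, which does not compare a list with other genes, gave 21 higher and 15 lower, and matched random lists 17 and 8. Spike-in scaling gave 13 and 6. Outside the estimated correlation and the random lists, 16 of the list results lost a call, 8 of them of meiosis and sporulation. Against random lists the proteasome (92.1 percentile) and marker lists (7.86) lost theirs. List medians kept their sign under 4 scalings in all 24 called lists. Only quantile normalization could have turned those, since median centring and spike-in scaling shift all genes alike and by less than any called median. Among the lists not called, medians changed sign in the pheromone, TCA, respiratory chain, cell wall, G2/M and zinc lists. With values floored at the control level, the called lists' medians moved by at most 0.061.

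Of 2117 alternatives of the 154 named results other than FLO1, 2078 gave the same call, 23 lost it, 12 gained it and 4 turned sign. Only results that passed in neither setting turned direction; the cause was not tested. PGM2 stood at -0.073 under median centring, and between -0.051 (without pGAL-FLO1 replicate 2) and 0.15 (without pGAL-FLO1 replicate 1) when arrays were left out, with -0.015 without wild-type replicate 2. GCY1 ranged from -0.014 (without pGAL-FLO1 replicate 2) to 0.27 (without pGAL-FLO1 replicate 1). Lists that turned, with their adjusted p: galactose 0.455 (quantile), 0.732 to 0.982 without single arrays, turning at 0.864 (without pGAL-FLO1 replicate 1), 0.982 (without wild-type replicate 2) and 0.958 (fry); respiratory chain 0.122 (quantile), 0.721 to 0.982 without single arrays, turning at 0.913 (without pGAL-FLO1 replicate 2), 0.982 (without wild-type replicate 2), 0.832 (spike-in) and 0.201 (fry); TCA cycle 0.706 (median centring), 0.781 (50th percentile filter), 0.953 (suffixed probe sets left out), 0.866 (without pGAL-FLO1 replicate 1), 0.845 (without wild-type replicate 1) and 0.949 (floored); cell wall integrity 0.753 (quantile); pheromone response 0.781 and G2/M 0.864 (50th percentile filter), and G2/M 0.429 to 0.827 without single arrays, turning at 0.827 (without pGAL-FLO1 replicate 2). Signal near the non-yeast controls limits folds of dim genes to bounds.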

Other observations

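Beyond the lists of the report, transfer RNA probe sets were lower in pGAL-FLO1: 47 of 62 tested fell, 0 rose (limma; 50 at an unadjusted p under 0.05) and the median was -1.16, ranging from -1.29 to -1.10 over 4 scalings. Of these probe sets 60 carry a shared-sequence suffix, so most report families of transfer RNA genes; of the 2 others, 1 fell. Small nucleolar RNAs, which guide the modification of ribosomal RNA, had 18 of 42 probe sets higher and 8 lower. Their median was 0.31 as deposited (0.18 to 0.37 over 4 scalings), against 0.16 for all tested probe sets as deposited. SNR41 (2.28) and SNR70 (1.89) were highest and SNR4 (-1.69) lowest. These RNAs were chosen after their values were seen. How far these probe set signals reflect mature transfer or small nucleolar RNA was not tested.

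Genes near chromosome ends had a higher median than all genes together. Of 284 measured genes among the 15 outermost protein-coding genes of each chromosome end, with flocculin, DAN/TIR and PAU genes left out, 130 rose (45.8%, against 36.3% of all genes) and 63 fell (22.2%, against 31.3%). The median was 0.31 against 0.07 for all genes, a gap of 0.24 that became 0.23 after quantile normalization. Median centring and spike-in scaling shift all genes alike and cannot change that gap. None of 10000 random gene sets matched on mean signal had a median as high, nor did any of 10000 sets of 32 runs of neighbouring genes away from the ends (highest 0.27). Without probe sets with a shared suffix, the median of the 255 remaining genes was 0.23 against 0.08, and that set was not tested against random ones. The set and its tests were chosen after the data were seen.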
